A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

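The deposited table of counts per gene was the only input to the tests. Its unit is a read count per the submitters' processing notes, which name Bowtie2 for alignment to sacCer3, HTSeq for counting and DESeq2 for the authors' comparisons, all without a version. The deposited FPKM table was compared with the counts and not used further. The authors' gene tables give a log2 fold change and an adjusted p-value per the file headers, and these were used only for comparison with the results here.

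Group membership came from the labels: 3 genotypes, log phase and 48 h, and strain numbers as replicates. The groups, the 11 comparisons, the main test and its alternatives were fixed before the data were examined. Genes were kept by filterByExpr, scaled by the trimmed mean of M-values and tested by the quasi-likelihood method of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) over all 12 libraries, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. The common dispersion was 0.0279 and the residual degrees of freedom were 6. Of the 7126 genes 562 had no count and 1058 were not tested. Here the log2 fold change is that of the edgeR fit, and every adjusted p of a gene comes from it unless DESeq2 1.42.0 is named. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made the tables of annotation and the plots.

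Gene lists were written from general knowledge of yeast before the data were examined, except the small nucleolar RNAs. They were tested by camera with a preset correlation of 0.01 between genes, again with an estimated correlation, and by fry, which asks whether a list moves without comparing it with other genes. The p-values of 40 lists were adjusted together in each comparison, and that of the added list was kept apart. Where an adjusted p is given with an estimated correlation, the reader has the stricter test.

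MMS2 and YSF3 are named throughout. Other genes were named by rule: up to 8 highest and 8 lowest with a gene symbol, an adjusted p under 0.05, a mean of at least 10 CPM and groups that did not overlap, up to 4 members with the smallest adjusted p of each list described, and genes of mating type for strain identity. Of the table's identifiers 6162 were matched to the annotation, 6048 by systematic name and 114 by symbol. Introns were annotated in 282 genes, and 604 genes had a near-identical copy at 95% identity over 50% of the length.

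The same strains were sampled in both phases. Strain was not in the main model and was a block in an alternative, and the residuals of a strain in the phases had r = -0.164 in the wild type and 0.0605 and 0.0374 in the mms2 and ysf3 deletions. Overlaps between the deletions were set beside 20 simulated draws that share the wild-type libraries, with each gene drawn independently. The tests were also tested on simulated data with known changes: 2-fold changes were recovered in 58.0% of cases for the wild-type phase change, 63.3% for the mms2 deletion in log phase and 67.4% at 48 h. Composition of the libraries was checked: small nucleolar RNA took 2.92 ± 0.401% of counts in the wild type in log phase, 4.84 ± 0.265% in the mms2 deletion and 5.32 ± 1.65% in the ysf3 deletion, and 5.20 ± 0.796%, 10.5 ± 1.53% and 9.72 ± 0.524% at 48 h (mean ± SD, n = 2). Ribosomal protein genes took 9.05 ± 0.271%, 10.6 ± 0.184% and 10.7 ± 1.93% in log phase, in the same order. At 48 h they took 1.47 ± 0.168%, 2.02 ± 0.185% and 1.81 ± 0.0721%.

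Splicing and intron retention were left out, since the table has no counts of introns or junctions. Alternatives were scaling by DESeq2 size factors or by library totals, the Wald test of DESeq2, a stricter adjusted p, a test against a fold of 1.5, only the libraries compared, strain number as a block, and leaving out 1 library at a time. Leaving out wild-type strain 1, crossing the strain numbers and adding the small nucleolar RNA list were chosen after the data were seen.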

Results

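Ribodepleted total RNA was sequenced from budding yeast of the BY background in 12 libraries. The wild type was compared with cells that lacked the single intron of MMS2 and with cells that lacked the single intron of YSF3. Each genotype had 2 independent strains, and each strain was sampled in log phase and after 48 h of culture in synthetic minimal medium with 2% glucose, which makes 6 groups of 2 libraries. The library totals ran from 4871513 to 16581925 counts. In log phase they were 14073723 and 15786978 in the wild type, 12522332 and 13866726 in the mms2 deletion and 13723072 and 14956893 in the ysf3 deletion. At 48 h they were 4871513 and 14999029, 5051438 and 15409749, and 9075505 and 16581925. The edgeR test covered 6068 of the 7126 genes in the table. Replicate libraries had Pearson's r of 0.990 to 0.997 across genes on the log2 scale, and the first principal component, which separated the phases, held 81.4% of the variance. Values are log2 fold changes ± an approximate error or CPM (counts scaled to library size) ± SD, with n = 2 libraries per group throughout. The approximate error is the size of the log2 fold change divided by the square root of the F statistic of its test. It is not a standard error of the fit, and with few counts it can be too small. For CRC1 at 48 h relative to log phase in the ysf3 deletion it was 0.38, beside a standard error of 0.59 from the authors.

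MMS2, which encodes a ubiquitin-conjugating enzyme variant used in DNA damage tolerance, did not pass the test in cells without its intron. Its level in log phase was 21.4 ± 0.977 CPM in the mms2 deletion and 16.2 ± 0.388 in the wild type, a log2 fold change of 0.40 ± 0.17 with an adjusted p of 0.0891. At 48 h the difference was 0.12 ± 0.17 with an adjusted p of 0.669. YSF3, which encodes a small subunit of the SF3b splicing complex, was counted at a low level of 3.32 ± 1.05 CPM in log phase in the ysf3 deletion and 1.93 ± 0.447 in the wild type. The log2 fold change was 0.77 ± 0.31 with an adjusted p of 0.0856, and 1.11 with a call past the threshold when replicate 2 of the ysf3 deletion in log phase was left out. At 48 h it was -0.10 ± 0.33 with an adjusted p of 0.897. Between the phases MMS2 rose by 0.42 ± 0.17 in the wild type with an adjusted p of 0.0454 and did not pass in the mms2 deletion (0.14, adjusted p of 0.493) or the ysf3 deletion (0.23, adjusted p of 0.25). YSF3 rose by 0.93 ± 0.33 in the mms2 deletion with an adjusted p of 0.0309 and did not pass in the wild type (0.37, adjusted p of 0.338) or the ysf3 deletion (-0.50, adjusted p of 0.182). With strain as a block, both of these phase calls were lost. The differences of these phase changes from the wild type did not pass either: MMS2 was at -0.29 ± 0.24 in the mms2 deletion (adjusted p of 0.682) and YSF3 at -0.87 ± 0.45 in the ysf3 deletion (adjusted p of 0.905). MMS2 (YGL087C) lies on chromosome VII of sacCer3 from 346406 to 346904, with its intron of 85 nt from 346809 to 346893. YSF3 (YNL138W-A) lies on chromosome XIV from 366033 to 366412, with its intron of 122 nt from 366036 to 366157. The table counts reads per gene and not per intron, so it holds no check of the deletions themselves.

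**Figure D1:**
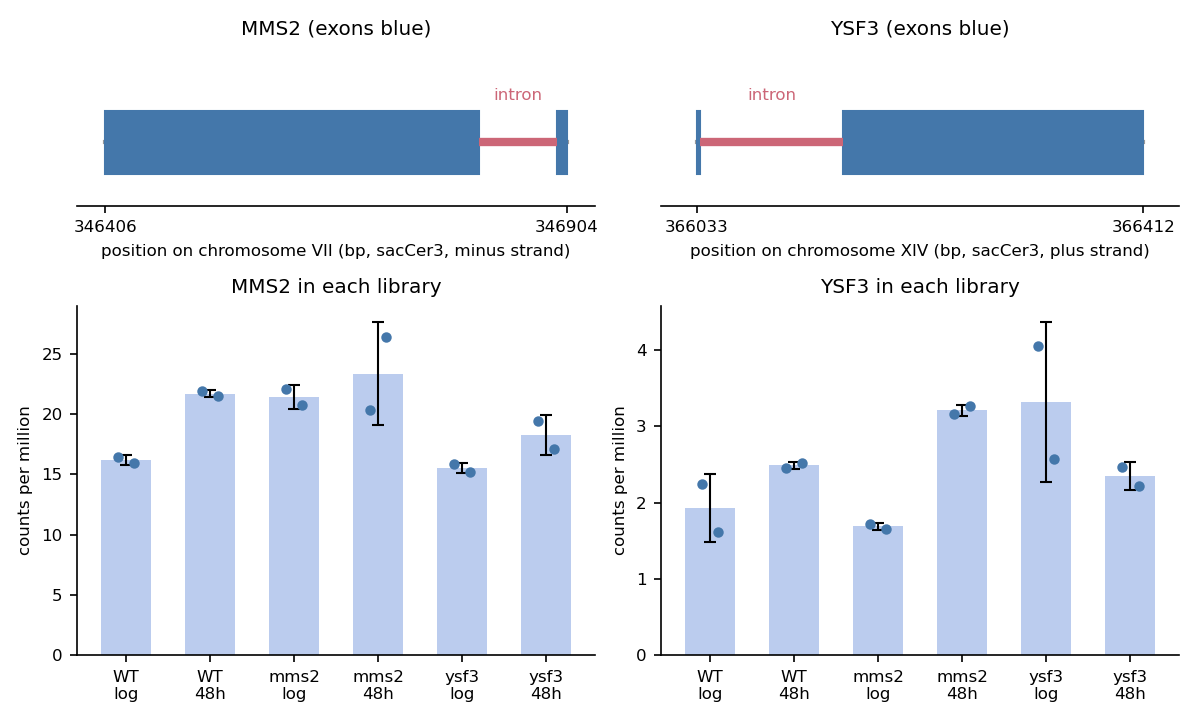
Gene models of MMS2 and YSF3 on sacCer3 (position in bp) above their levels in CPM in each library (points), with the group mean (bar) and SD (error bar, n = 2). MMS2 ran from a mean of 15.5 in the ysf3 deletion in log phase to 23.4 in the mms2 deletion at 48 h, and YSF3 from 1.69 to 3.32.

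The wild-type comparison of 48 h with log phase asked which genes nutrient depletion turns down or up when both introns are present. Of the 135 tested cytosolic ribosomal protein genes 132 fell at 48 h, with a median log2 fold change of -2.67 (adjusted p of 1.0e-30 in the competitive test of gene lists, lost with an adjusted p = 0.267 with an estimated correlation). RPS22A, a small-subunit protein gene, fell by 4.54 ± 0.23 on the log2 scale and RPL22A by 3.87 ± 0.21. Among the highest genes, the malate synthase gene MLS1 went from 0.939 to 580 CPM, and SPG4, which is needed for survival in stationary phase at high temperature, from 1.85 to 1396. The small heat shock protein gene HSP12 rose by 9.92 ± 0.54 and PHM7 by 8.80 ± 0.31.

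Ribosome biogenesis genes and translation factors fell too, with list calls that were lost, each with an adjusted p = 0.128 with an estimated correlation. Of 134 ribosome biogenesis genes 119 fell and 0 rose, among them BRX1 at -3.20 ± 0.12 and NIP7 at -4.04 ± 0.20, both needed for assembly of the large subunit. Of 38 translation factors 35 fell, including the elongation factor gene TEF4 at -3.40 ± 0.19 and the helicase gene TIF1 at -3.21 ± 0.19. Outside translation, 14 of 16 purine biosynthesis genes fell, a call that held with an adjusted p = 0.0446 with an estimated correlation, with ADE17 at -3.63 ± 0.20 and ADE1 at -3.42 ± 0.15. Calls of the next groups were lost, with an adjusted p = 0.141 with an estimated correlation for ergosterol and cell cycle genes and 0.514 for histones. Of 25 ergosterol genes 21 fell, with ERG2 at -2.79 ± 0.18. Of 31 cell cycle and replication genes 18 fell and 1 rose, and the mitotic cyclin genes CLB2 and CLB1 reached -4.80 ± 0.30 and -4.45 ± 0.19. Of 10 histone genes 8 fell, among them HTA1 at -1.99 ± 0.18. The other lowest genes were UTR2, which encodes a cell wall transglycosylase, at -6.15 ± 0.20, the oligopeptide transporter gene OPT2 at -5.15 ± 0.31, the transcription factor gene SFG1 at -4.82 ± 0.29, the glutamate dehydrogenase gene GDH2 at -4.60 ± 0.30, and INA1 and AIM20, both at -4.49.

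Many genes of respiration and of carbon recovery rose. The glyoxylate and stationary phase list calls held, each with an adjusted p = 0.0446 with an estimated correlation, and those of the respiratory chain (0.141), trehalose and glycogen (0.141), mitochondrially encoded proteins (0.514), autophagy (0.0528) and peroxisomal genes (0.128) were lost by that adjusted p with an estimated correlation. All 28 tested nuclear genes of the respiratory chain rose, with the cytochrome c isoform gene CYC7 at 6.07 ± 0.25 and the succinate dehydrogenase gene SDH1 at 4.83 ± 0.25. Of 8 proteins encoded in the mitochondrial genome 7 rose, among them COX3 at 3.76 ± 0.39. Of 21 genes of the glyoxylate cycle and gluconeogenesis 17 rose, including the carnitine acetyltransferase gene YAT1 at 7.55 ± 0.16 and the phosphoenolpyruvate carboxykinase gene PCK1 at 5.88 ± 0.21. Of 21 trehalose and glycogen genes 19 rose, with GAC1, a targeting subunit of the glycogen synthase phosphatase, at 6.23 ± 0.31. Of 22 stationary phase genes 18 rose, of 40 autophagy genes 31 rose with ATG1 at 3.51 ± 0.17 and ATG8 at 3.37 ± 0.22, and of 24 peroxisomal genes 19 rose with the acyl-CoA oxidase gene POX1 at 5.14 ± 0.26. Glycolysis genes split, with 6 higher and 14 lower: the hexokinase gene HXK1 rose by 5.63 ± 0.30 while HXK2 reached -2.86 ± 0.21. Of 19 hexose transporter genes 8 rose and 2 fell, without a list call (adjusted p of 0.0573, and 0.514 with an estimated correlation), although with strain as a block the adjusted p was 0.0466. HXT5 rose by 7.88 ± 0.26 and the low-affinity transporter gene HXT1 was at -3.76 ± 0.28.

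In all, 1990 genes rose and 2083 fell in the wild type, at an adjusted p under 0.05 by edgeR. Adjusted over the list alone, 132 ribosomal protein genes fell and 0 rose. DPA10 had 0 counts in log phase and was at least 2136-fold higher at 48 h, with a bound of 1121 and 1015 without replicate 1 and 2 in log phase, and of 1195 without replicate 2 at 48 h. Genes of the ribosomal DNA stood high but unevenly between replicates. RDN37-1 had 469 and 171 counts in replicates 1 and 2 at 48 h and was at least 321-fold higher, and its call ended without replicate 1 or 2 in log phase (bounds of 168 and 152) and without replicate 1 at 48 h (114), while the bound was 941 without replicate 2 at 48 h. RDN37-2 had 555 and 217 counts and a ratio of 580 with a counting interval of 160 to 4798. Its call also ended without replicate 1 in log phase (at least 203-fold), replicate 2 in log phase (276) or replicate 1 at 48 h (217), and its ratio was 1670 without replicate 2 at 48 h. TAR1, encoded on the opposite strand of a ribosomal DNA copy, had a ratio of 813 with an interval of 145 to 32167, which became 427 and at least 129 without replicate 1 and 2 in log phase, and 393 and 2076 without replicate 1 and 2 at 48 h. With both libraries of wild-type strain 1 left out the calls of TAR1, RDN37-1 and RDN37-2 ended, with adjusted p of 0.122, 0.17 and 0.249. In the mms2 deletion at 48 h RDN37-2 had 575 counts in replicate 1 and 1 in replicate 2, and removal of ribosomal RNA can differ between libraries. These loci are near-identical copies or overlap each other, so their counts cannot be assigned to 1 of them. Counting intervals and floors, here 3 counts over the group, cover counting error only.

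At 48 h relative to log phase, 2027 genes rose and 1863 fell in the mms2 deletion, and 2057 rose and 1999 fell in the ysf3 deletion. Ribosomal protein genes fell in both, 131 of 135 with a median of -2.52 in the mms2 deletion and 134 of 135 with a median of -2.81 in the ysf3 deletion (adjusted p = 0.232 and 0.225 with an estimated correlation). RPS22A reached -3.94 ± 0.22 and -4.22 ± 0.22. The glyoxylate list rose in 17 of 21 genes in each deletion, with MLS1 at 9.74 ± 0.24 in the mms2 deletion and 9.42 ± 0.24 in the ysf3 deletion, and the stationary phase list in 19 and 20 of 22 genes. These calls held, with an adjusted p = 0.0417 in the mms2 and 0.0477 in the ysf3 deletion with an estimated correlation.

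In the mms2 deletion the highest genes also included DPA10 at 10.79 ± 0.54, SPG4 at 8.95 ± 0.29, HSP12 at 8.83 ± 0.51, SIP18, a desiccation tolerance gene, at 8.10 ± 0.31, HSP26 at 8.08 ± 0.31, the succinate-fumarate transporter gene SFC1 at 8.07 ± 0.22 and HXT5 at 8.05 ± 0.26. Its lowest genes were UTR2 at -6.41 ± 0.20, OPT2 at -5.47 ± 0.32, INA1 at -5.30 ± 0.48, AIM20 at -4.89 ± 0.31, SFG1 at -4.52 ± 0.28, HXT1 at -4.50 ± 0.28, the mating-type endonuclease gene HO at -4.43 ± 0.41 and PHO12, which has the near-identical copy PHO11, at -4.32 ± 0.38. In the ysf3 deletion HSP12 rose by 10.37 ± 0.55, DPA10 by 10.28 ± 0.54, SPG4 by 10.22 ± 0.32, PHM7 by 9.87 ± 0.33, HXT5 by 9.27 ± 0.28, SIP18 by 9.08 ± 0.33 and the mitochondrial carnitine carrier gene CRC1 by 8.64 ± 0.38. UTR2 at -6.16 ± 0.20, OPT2 at -5.24 ± 0.31, INA1 at -5.17 ± 0.46, SFG1 at -4.98 ± 0.28, CLB2 at -4.83 ± 0.30, GDH2 at -4.35 ± 0.30, CLB1 at -4.35 ± 0.19 and AIM20 at -4.32 ± 0.29 were lowest. In log phase DPA10 had only 1 and 3 counts in the mms2 deletion and 2 and 2 in the ysf3 deletion. CRC1 had 1 and 3 in the ysf3 deletion, so the size of these rises rests on few counts. The approximate error beside each of them can be too small.

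Against the wild type in log phase, the comparison that asks what loss of 1 intron does during growth, the mms2 deletion had more ribosomal protein mRNA and more small nucleolar RNA. As a share of all counts, ribosomal protein genes took 10.6 ± 0.184% in the mms2 deletion and 9.05 ± 0.271% in the wild type. Of the 135 ribosomal protein genes 69 rose and 5 fell, with a median of 0.66 and a list call (adjusted p of 2.5e-13) that was lost with an adjusted p = 0.558 with an estimated correlation. RPL30, whose protein represses splicing of its own transcript, rose by 2.29 ± 0.31 and RPS29A by 2.51 ± 0.33. The median was 0.57 in the 89 members with an intron, of which 42 rose, and 0.92 in the 46 without, of which 27 rose. Of 42 small nucleolar RNAs, which guide modification and processing of ribosomal RNA, 26 rose and 0 fell with a median of 1.48 (p = 4.5e-13 by the list test across genes, and p = 0.135 with an estimated correlation). That list was added after the values were seen. The rise was not limited to it. The RNAs of RNase MRP and RNase P, named after their values were seen, rose by 1.78 and 1.59. They also passed in the other comparisons of a deletion with the wild type, at 1.65 to 2.26, while telomerase RNA passed in none. snR49 rose by 4.52 ± 0.72, snR4 by 2.95 ± 0.42, snR5 by 2.86 ± 0.55, snR44, which lies within RPS22B, by 2.5 ± 0.35, snR189 by 2.42 ± 0.50, snR128 by 2.37 ± 0.34 and snR17b, a U3 gene, by 2.33 ± 0.43. Replicates 1 and 2 of the mms2 deletion were uneven for snR49 (249 and 1037 counts) and snR5 (185 and 599), and closer for snR44 (1235 and 1813).

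The list calls for the next groups in the mms2 deletion in log phase were lost, each with an adjusted p = 0.558 with an estimated correlation. Of 21 glycolysis genes 11 rose and 0 fell, including the enolase gene ENO2 at 2.02 ± 0.28, TDH3 at 1.76 ± 0.30 and PGK1 at 1.35 ± 0.24. Histone genes rose in 7 of 10 cases, with HTA2 at 1.33 ± 0.32, and mitochondrially encoded proteins in 5 of 8, with OLI1 at 1.60 ± 0.30. Amino acid biosynthesis genes rose in 22 of 57 cases and fell in 1, with THR1 at 1.77 ± 0.25, and 12 of 24 oxidative stress genes rose, with the peroxiredoxin gene AHP1 at 1.93 ± 0.31. Ribosome biogenesis went the other way from the ribosomal proteins: 48 of 134 genes fell and 9 rose, among them SSF1 at -0.86 ± 0.16. Of 65 spliceosome genes 17 fell and 4 rose, with the U1 protein gene YHC1 at -0.80 ± 0.16 and the Sm protein gene SMX2 at 2.16 ± 0.33. Intron-containing genes other than ribosomal protein genes did not move as a group: 29 of 169 rose and 14 fell, and their median of 0.03 became -0.11 with library totals as the scaling.

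The lowest genes of the mms2 deletion in log phase were genes of the alpha mating type, which stood higher in log phase in wild-type strain 1 than in any other strain. The alpha-factor gene MF(ALPHA)1 had 2 counts in the mms2 deletion, and its ratio of wild type to deletion was 2039 with a counting interval of 564 to 16845. Without replicate 1 of the wild type it was 3.81 with an interval of 0.624 to 40.1, without replicate 2 of the wild type 4289, without replicate 1 of the mms2 deletion 1064, and at least 650-fold without replicate 2 of the mms2 deletion. The a-factor receptor gene STE3 was at -7.42 ± 1.85, the alpha-agglutinin gene SAG1, which read 24.4 and 27.5 CPM in the mms2 deletion and 1518 and 32.9 in the wild-type strains, at -4.90 ± 1.21 and the a-factor barrier gene AFB1 at -3.89 ± 1.22. AUA1, which overlaps a gene on the opposite strand, was at -1.96 ± 0.56, CSS1 at -1.76 ± 0.57, the cell wall mannoprotein gene HPF1 at -1.65 ± 0.44 and BIL1 at -1.44 ± 0.24. Replicates 1 and 2 of the mms2 deletion were uneven for AUA1 (189 and 31 counts), CSS1 (318 and 70) and HPF1 (530 and 225). The U2 spliceosomal RNA gene LSR1 and the signal recognition particle RNA gene SCR1, both named after their values were seen, were at -0.94 ± 0.27 and 0.88 ± 0.29 and passed the test.

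In log phase 842 genes rose and 809 fell in the mms2 deletion, with 51.0% of the changed genes higher. Scaling by library totals made that share 30.8% and shifted the median of all genes by -0.14. The count fell to 0 without replicate 2 of the mms2 deletion, to 6 without replicate 2 of the wild type, and to 1059 without replicate 1 of the mms2 deletion. Adjusted over the list alone, 74 ribosomal protein genes rose and 10 fell.

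In the ysf3 deletion in log phase 73 of the 135 ribosomal protein genes rose and 8 fell, with a median of 0.75 and a list call (adjusted p of 1.5e-14) that was lost with an adjusted p = 0.628 with an estimated correlation. They were led by RPL30 at 2.76 ± 0.31, RPS29A at 2.77 ± 0.33 and RPL7A at 2.44 ± 0.36, while RPL37A, 1 of the intron-containing members, fell by 1.49 ± 0.26. The median was 0.62 in the members with an intron and 0.91 in those without. As a share of all counts, ribosomal protein genes took 12.1% and 9.36% in replicates 1 and 2, beside 9.25% and 8.86% in the wild type. Small nucleolar RNAs rose in 30 of 42 cases with a median of 1.94 (p = 6.7e-21 by the list test across genes, and p = 0.0667 with an estimated correlation), among them snR49 at 4.44 ± 0.72, snR5 at 3.62 ± 0.56, snR4 at 3.38 ± 0.43, snR128 at 3.05 ± 0.35, snR17b at 2.98 ± 0.44, snR37 at 2.95 ± 0.46 and snR83 at 2.78 ± 0.38. ERG28, a scaffold of the ergosterol enzymes, rose by 2.83 ± 0.35.

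The list calls for the next groups in the ysf3 deletion in log phase were lost, each with an adjusted p = 0.608 with an estimated correlation. Glycolysis genes rose in 16 of 21 cases, with ENO2 at 2.2 ± 0.28, TDH3 at 2.12 ± 0.30 and PGK1 at 1.94 ± 0.24. Of 10 histone genes 7 rose, with HTA2 at 1.81 ± 0.33. Of 19 iron regulon genes 9 rose, including the siderophore transporter genes ENB1 at 1.79 ± 0.34 and ARN1 at 1.85 ± 0.38 and the mRNA decay factor gene TIS11 at 2.04 ± 0.40. Ribosome biogenesis genes fell in 68 of 134 cases and rose in 5, with NSA1 at -0.92 ± 0.14 and RPF2 at -0.84 ± 0.13. Of the 65 spliceosome genes 19 fell and 4 rose, with SME1 at -0.94 ± 0.18. Intron-containing genes other than ribosomal protein genes rose in 29 and fell in 18 of 169 cases, with a median of 0.01 that became -0.16 under library totals. The alpha-cell genes of wild-type strain 1 again stood lowest, MF(ALPHA)1 at -10.07 ± 2.66 and STE3 at -6.67 ± 1.74. They were followed by BIL1 at -1.75 ± 0.25, AUA1 at -1.69 ± 0.55, the cytochrome oxidase assembly gene PET191 at -1.58 ± 0.30, the RNA polymerase subunit gene RPC10 at -1.46 ± 0.17 and RTC3 at -1.46 ± 0.41.

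In log phase 830 genes rose and 822 fell in the ysf3 deletion, with 50.2% of the changed genes higher. Library totals made that share 29.8% and shifted the median of all genes by -0.16, and the count fell to 38 without replicate 2 of the wild type. Adjusted over the list alone, 81 ribosomal protein genes rose and 10 fell.

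**Figure D2:**
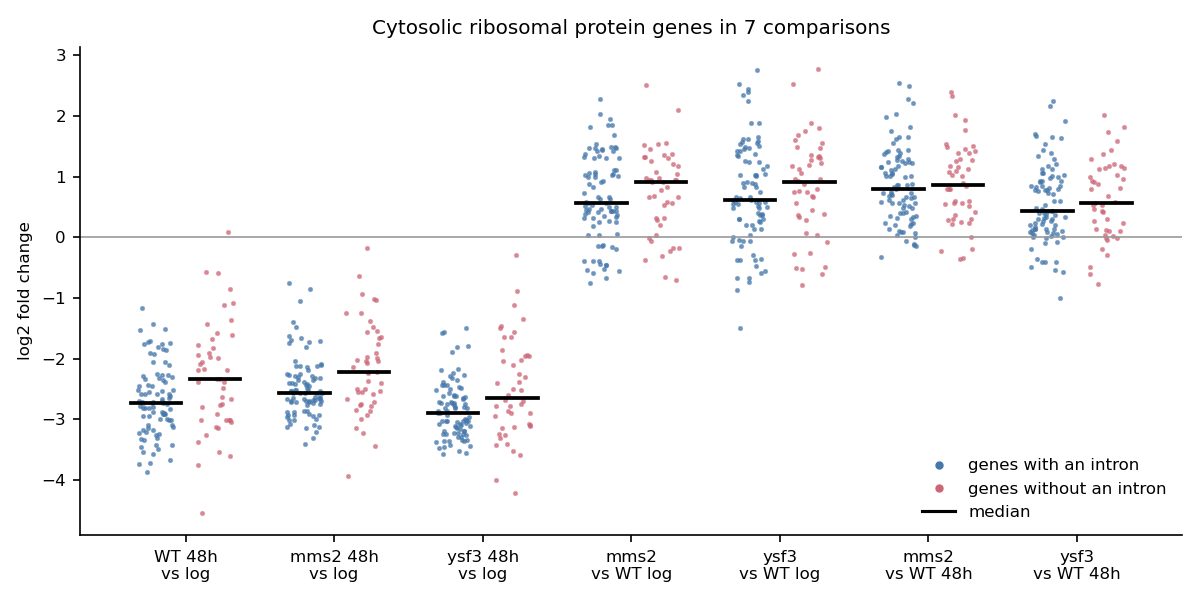
Log2 fold changes of the cytosolic ribosomal protein genes (points, 1 per gene) with their median (line) in 7 comparisons, for genes with and without an intron. Medians of the genes with an intron were -2.72 for 48 h in the wild type and 0.57, 0.62, 0.80 and 0.44 for the mms2 and ysf3 deletions in log phase and at 48 h.

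At 48 h, the comparison that asks how levels differ from the wild type after depletion, ribosomal protein mRNA stood higher in the mms2 deletion. It does not measure how far depletion turned genes down, which the interaction below does. Of the 135 genes 68 rose and 0 fell, with a median of 0.83 and a list call (adjusted p of 3.5e-24) that was lost with an adjusted p = 0.48 with an estimated correlation. RPL1B, RPL1A and RPS29A were at 2.02 ± 0.33, 1.94 ± 0.32 and 2.40 ± 0.40. The median was 0.80 in the 89 members with an intron and 0.87 in those without. Small nucleolar RNAs rose in 33 of 42 cases with a median of 2.32 (p = 4.2e-32 by the list test across genes, and p = 0.0323 with an estimated correlation), among them snR32 at 3.28 ± 0.53, snR3 at 3.27 ± 0.72, snR5 at 3.12 ± 0.54, snR49 at 3.01 ± 0.66, snR63 at 2.76 ± 0.45, snR37 at 2.67 ± 0.45, snR128 at 2.61 ± 0.34 and snR46 at 2.60 ± 0.47. The mms2 replicates were uneven for some of them, at 25.8 ± 27.3 CPM for snR3 and 318 ± 241 for snR32. They were closer for others, at 318 ± 29.2 for snR128 and 59.1 ± 6.28 for snR49.

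Mitochondrial and carbon genes were higher too in the mms2 deletion at 48 h, with list calls that were lost, each with an adjusted p = 0.48 with an estimated correlation. Of 28 respiratory chain genes 17 rose, with COR1 at 1.34 ± 0.19 and RIP1 at 1.55 ± 0.23, both of the cytochrome bc1 complex. Of 8 mitochondrially encoded proteins 6 rose, of 21 glyoxylate and gluconeogenesis genes 11 rose and 1 fell, with SFC1 at 1.61 ± 0.14 and the fructose bisphosphatase gene FBP1 at 1.62 ± 0.23, and of 21 glycolysis genes 12 rose, with TPI1 at 1.75 ± 0.32. The lowest genes were the allantoin permease gene DAL4 at -1.80 ± 0.34, the meiotic recombinase gene DMC1 at -1.79 ± 0.42, SPG1 at -1.36 ± 0.31, the sulfur transcription factor gene MET32 at -1.33 ± 0.30, the aldehyde dehydrogenase gene ALD3 at -1.24 ± 0.24, SLZ1 at -1.17 ± 0.26, HBT1 at -1.12 ± 0.21 and the peroxisomal fatty acid transporter gene PXA1 at -1.09 ± 0.18.

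At 48 h 518 genes rose and 127 fell in the mms2 deletion, with 80.3% higher, a share that library totals made 53.0% with a shift of the median of all genes by -0.17. The count fell to 0 without replicate 1 of the wild type, which is strain 1, and to 1 without replicate 2 of the mms2 deletion. With both libraries of that strain left out it was also 0. Adjusted over the list alone, 94 ribosomal protein genes rose and 0 fell.

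By edgeR on all libraries fewer single genes passed at 48 h in the ysf3 deletion than in the mms2 deletion. That order turned with only the libraries compared, and the authors listed 224 genes for the ysf3 and 179 for the mms2 deletion. Of the ribosomal protein genes 16 rose and 0 fell in the ysf3 deletion, with a median of 0.49. The list call (adjusted p of 7.0e-15 in the competitive test) was lost with an adjusted p = 0.597 with an estimated correlation. RPL4A, RPL2B and RPL1B were at 1.18 ± 0.20, 1.38 ± 0.25 and 1.82 ± 0.33. The median was 0.44 in the members with an intron and 0.57 in those without. Small nucleolar RNAs rose in 24 of 42 cases with a median of 2.04 (p = 3.3e-36 by the list test across genes, and p = 0.0228 with an estimated correlation), among them snR49 at 2.90 ± 0.66, snR5 at 2.85 ± 0.53, snR37 at 2.72 ± 0.46, snR32 at 2.68 ± 0.52, snR45 at 2.52 ± 0.31, snR36 at 2.51 ± 0.40, snR128 at 2.5 ± 0.33 and snR44 at 2.29 ± 0.35. Of 21 glycolysis genes 10 rose (call lost with an adjusted p = 0.597 with an estimated correlation), with PGK1 at 1.49 ± 0.24 and TPI1 at 1.75 ± 0.32. DAL4 was lowest at -1.68 ± 0.32, then the mitochondrial thioredoxin gene TRX3 at -0.94 ± 0.21, the ubiquitin-like protein gene RUB1 at -0.89 ± 0.18, SEM1 and TMH11 both at -0.88 ± 0.20, RGI2 at -0.82 ± 0.19, NHP6B, whose locus overlaps a gene on the same strand, at -0.81 ± 0.16, and POP4, a subunit of RNase P and RNase MRP, at -0.81 ± 0.15.

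At 48 h 151 genes rose and 17 fell in the ysf3 deletion, with 89.9% higher, a share that library totals made 73.1% with a shift of the median of all genes by -0.11. The count was 0 without replicate 1 of the wild type, without replicate 1 of the ysf3 deletion, without replicate 2 of the ysf3 deletion, or without both libraries of wild-type strain 1. Adjusted over the list alone, 59 ribosomal protein genes rose and 6 fell.

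**Figure D3:**
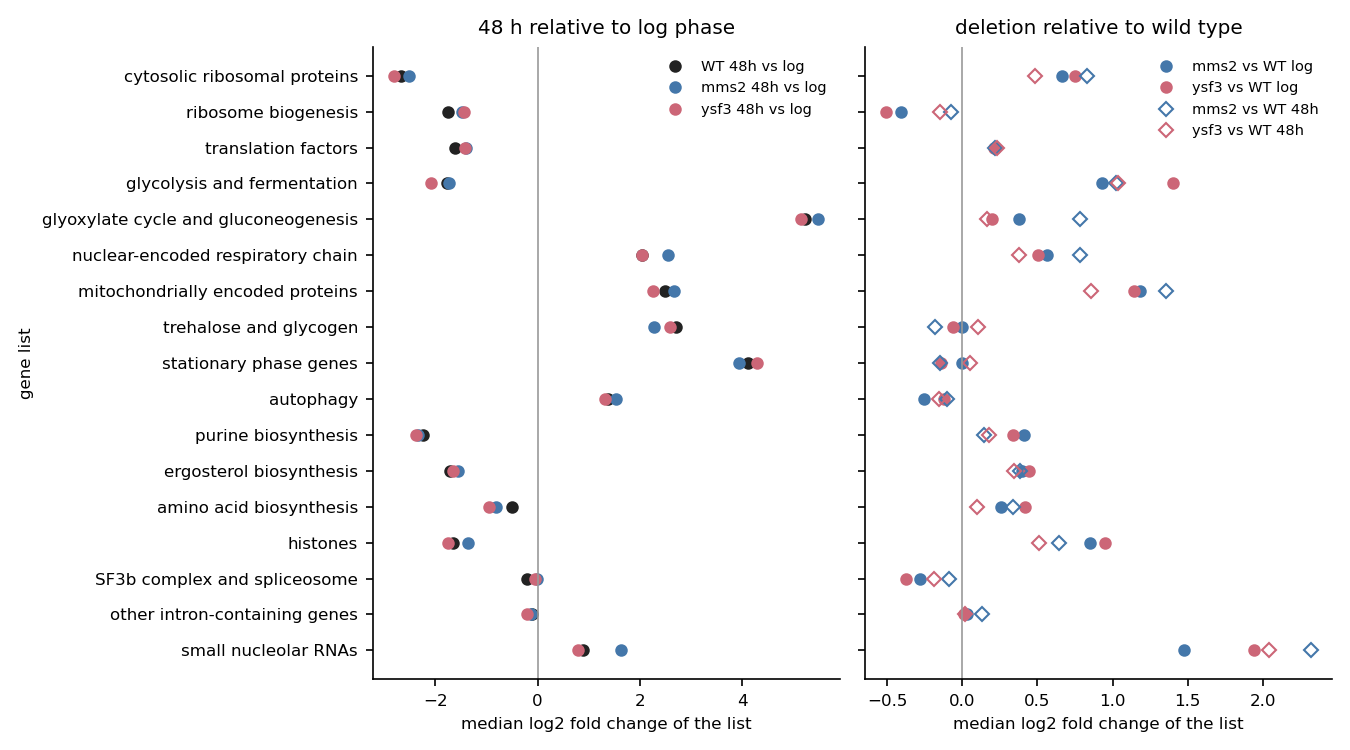
Median log2 fold change of 17 gene lists at 48 h relative to log phase in each genotype (left) and in each deletion relative to the wild type (right). The ribosomal protein genes stood at -2.67, -2.52 and -2.81 in the wild type, the mms2 and the ysf3 deletion to the left and at 0.66, 0.75, 0.83 and 0.49 to the right; right-hand medians close to 0 (other intron-containing, trehalose and glycogen, stationary phase and, at 48 h, amino acid and purine genes) changed sign under other scalings.

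The genes called in the deletions overlapped, although MMS2 and YSF3 have unrelated functions. In log phase 628 genes were higher in both, of 842 in the mms2 and 830 in the ysf3 deletion, where independent lists would share 115, and 586 of 809 and 822 were lower in both, against 110. At 48 h 137 of 518 and 151 were higher in both against 12.9, and 10 of 127 and 17 were lower in both against 0.356. No gene was called in opposite directions (0 in each phase). The shared members included RPL30, RPS29A, ENO2, TDH3, snR49, snR5 and snR128 in log phase. Across genes, which are not independent replicates, the log2 fold changes of the deletions had r = 0.855 in log phase and 0.845 at 48 h. Both deletions were compared with the same wild-type libraries. In 20 simulated draws without any effect, that sharing gave a mean r of 0.484 and 0.511 and at most 1 shared gene per direction. Each gene was drawn independently of the others, so variation of a library that is common to many genes was left out. The draws therefore cannot tell how much overlap such variation in the wild-type libraries would give. The covariance was 0.450 and 0.256, beside 0.0546 and 0.0554 in the simulated draws. With a different single wild-type library for each deletion, a division made after the data were seen, r was 0.578 or 0.633 in log phase and 0.584 or 0.532 at 48 h, and the covariance 0.370 or 0.393 and 0.242 or 0.254. In each of these runs 1 deletion had few or no calls, which kept the number of shared calls low whatever the cause. The shared calls of these runs therefore cannot tell how much of the excess comes from the shared wild-type libraries. The shared count in log phase was 0 for both directions without replicate 2 of the mms2 deletion. Without replicate 2 of the wild type it was 1 higher and 5 lower, and the lower count was 330 without replicate 1 of the mms2 deletion and 313 without replicate 2 of the ysf3 deletion. At 48 h both counts were 0 without replicate 1 of the wild type, replicate 2 of the mms2 deletion or either replicate of the ysf3 deletion, and the lower count was 20 without replicate 2 of the wild type.

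**Figure D4:**
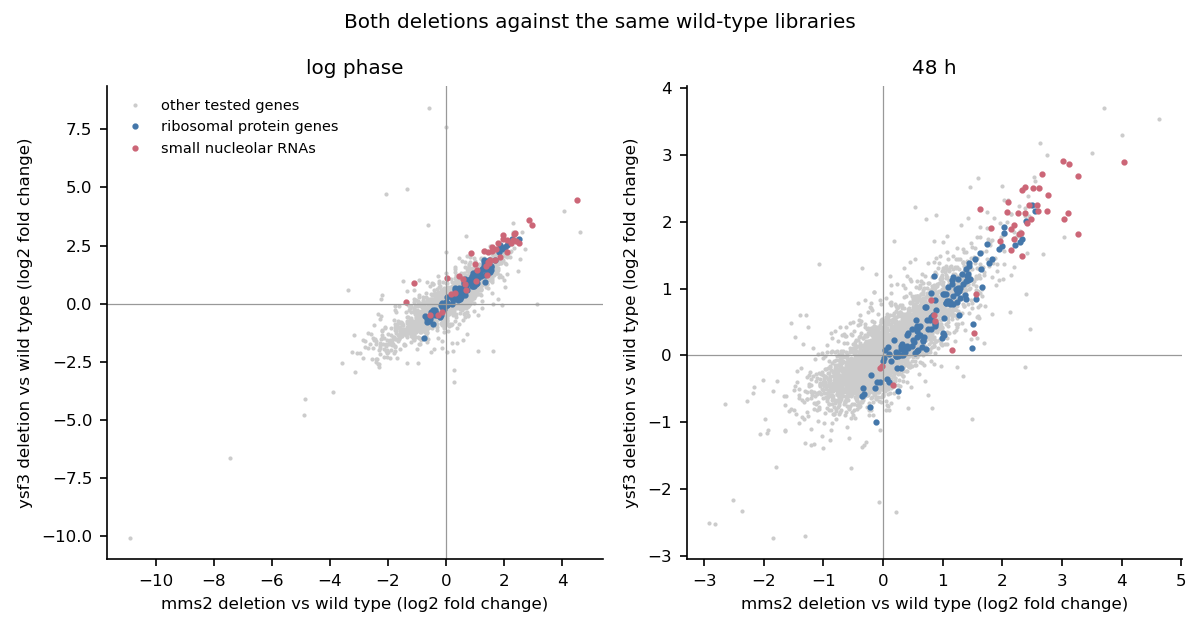
Log2 fold change of each tested gene in the mms2 deletion (horizontal) and in the ysf3 deletion (vertical) relative to the same wild-type libraries, in log phase and at 48 h. Across genes r was 0.855 and 0.845, and small nucleolar RNAs lay to the upper right with medians of 1.48 to 2.32.

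The deletions were compared with each other to ask what sets them apart. By edgeR 0 genes differed in log phase and 0 at 48 h, while 232 and 374 genes had an unadjusted p under 0.05 and DESeq2 called 4 and 11. MMS2 was 0.47 ± 0.17 higher in the mms2 deletion in log phase with an adjusted p of 0.999, and YSF3 was at -0.96 ± 0.32 with an adjusted p of 0.999. At 48 h they were at 0.37 ± 0.17 and 0.46 ± 0.33, with adjusted p of 0.792 and 0.817. The ribosomal protein median was -0.06 in log phase and 0.28 at 48 h, and the second value passed the competitive test with an adjusted p of 1.8e-10 but had an adjusted p = 0.842 with an estimated correlation.

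Whether the phase change itself differs from that of the wild type was tested as an interaction, since the study's question is repression under starvation. By edgeR 0 genes passed in the mms2 deletion, with 568 at an unadjusted p under 0.05 and 19 by DESeq2, and 0 in the ysf3 deletion, with 284 at an unadjusted p under 0.05 and 0 by DESeq2. Without replicate 2 of the wild type in log phase the counts were 2 and 3, and without replicate 1 of the mms2 deletion in log phase the first was 1. The ribosomal protein genes had a median interaction of 0.19 in the mms2 deletion with an adjusted p of 0.0915, and of -0.15 in the ysf3 deletion with an adjusted p of 0.00176. The second call was lost, with an adjusted p = 0.864 with an estimated correlation. The first median was -0.22 without both libraries of wild-type strain 1, and the second was 0.08 without replicate 2 of the wild type at 48 h and 0.07 without replicate 1 of the ysf3 deletion in log phase. In tests on simulated data, run for the mms2 interaction only, 20% of 2-fold and 87.2% of 3-fold interactions were recovered. Thus the higher ribosomal protein level of the deletions at 48 h stood beside a level already higher in log phase. By edgeR on all 12 libraries no gene's phase change passed as different from that in the wild type.

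Strain identity was read from genes of mating type. Wild-type strain 1 had more of the alpha-cell gene STE3 than of the a-cell gene STE2, and the other 5 strains had more STE2. In log phase strain 1 read 336 CPM for MF(ALPHA)1 and 578 for STE3, against 0.299 and 4.31 in wild-type strain 2, while the alpha-factor receptor gene STE2 read 9.59 against 786. The difference between the wild-type strains also enters the wild-type phase comparison, where SAG1 was at -4.09 ± 1.17, MF(ALPHA)1 at -5.13 ± 1.89 and STE2 at -3.62 ± 1.35. Without strain 1 these genes stood at 0.16, 0.52 and -3.88.

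**Figure D5:**
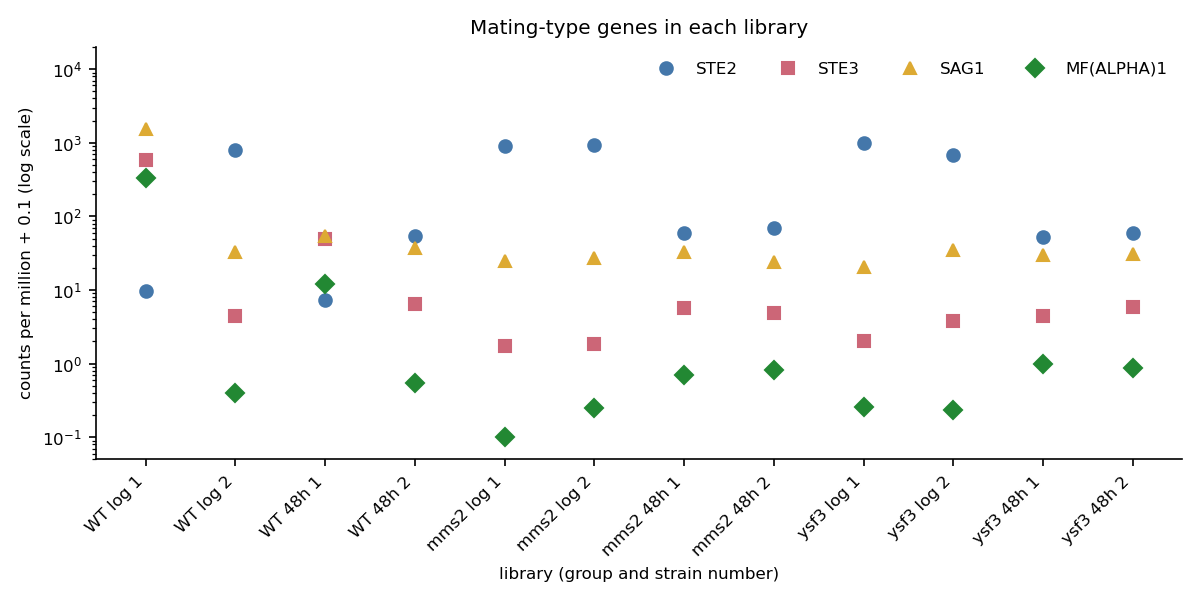
CPM plus 0.1 (log scale) of 4 mating-type genes in each of the 12 libraries. Both libraries of wild-type strain 1 had more STE3 than STE2 (578 and 9.59 in log phase), unlike the other 10.

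The authors' own gene tables, limited to an adjusted p under 0.001 by DESeq2, listed 2865, 2690 and 2629 genes for the phase change in the wild type, the mms2 and the ysf3 deletion. Of these 2853, 2684 and 2619 were also called here, at the looser adjusted p under 0.05 by edgeR. Against the wild type they listed 547 and 179 genes for the mms2 deletion in log phase and at 48 h, of which 520 and 170 were called here at that threshold, and 309 and 224 for the ysf3 deletion, of which 307 and 127 were called here. At an adjusted p under 0.001 edgeR called none in these comparisons. DESeq2 run here at an adjusted p under 0.001 shared 365 and 156 of the authors' genes for the mms2 deletion and 292 and 111 for the ysf3 deletion. Every gene of these 7 tables had the same sign here. Ribosomal protein genes were listed as higher in 64, 30, 46 and 32 cases in these 4 tables, in that order. Between the deletions the authors listed 7 genes at 48 h. The deposited signs are opposite to mms2 relative to ysf3 as computed here, so the table was read as ysf3 relative to mms2 and its signs were turned, which gives SFC1 and DAL5 as higher in the mms2 deletion and YJL225C, CTT1, TKL2, SLZ1 and BIO5 as lower, and 0 of them passed here. Their table for log phase held no gene.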

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

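The values here are medians over gene lists of the difference between the phase change of a deletion and that of the wild type. They stood out because the competitive test found a difference between genotypes, and each call was lost with an estimated correlation. The tests of length, of expression level and of the mating type of wild-type strain 1 for the ribosomal protein and small nucleolar RNA genes were written before their results were seen. The tests of GC content, on 15S and 21S ribosomal RNA and on a swap or mixture of strain 1 were chosen after the result was seen.

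In the mms2 deletion the lists with a higher phase change were mitochondrial ribosomal proteins at 0.26, ribosome biogenesis at 0.25, the respiratory chain at 0.39, ATP synthase at 0.31, the TCA cycle at 0.61 and alpha-cell genes at 5.06. The alpha-cell values here and for the ysf3 deletion rest on wild-type strain 1, without which the wild-type phase median of that list turned from -4.09 to 0.52. Those with a lower one were trehalose and glycogen at -0.18, oxidative stress at -0.13, peroxisomal genes at -0.19 and nitrogen catabolite repression at -0.37. The adjusted p with an estimated correlation was 0.728 for each.

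In the ysf3 deletion the lists with a higher phase change were mitochondrial ribosomal proteins at 0.23, ribosome biogenesis at 0.38, hexose transporters at 0.80, SF3b and spliceosome genes at 0.17 (a call lost with strain as a block, with an adjusted p of 0.0571) and alpha-cell genes at 4.34. Ribosomal protein genes stood at -0.15, with -0.15 in those with and -0.15 in those without an intron. Glycolysis was at -0.22, oxidative stress at -0.091, amino acid biosynthesis at -0.31, sulfur amino acids at -0.14, purine biosynthesis at -0.24, the iron regulon at -0.53, nitrogen catabolite repression at -0.29, histones at -0.27, cell cycle genes at -0.17 and autophagy at -0.042, which became 0.01 with library totals. The adjusted p with an estimated correlation ran from 0.461 to 0.864.

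Ribosomal protein and small nucleolar RNA genes were higher in both deletions than in the wild type. Length was taken over the gene with its introns, so it exceeds the transcript length of the 89 ribosomal protein genes with an intron. The median of all 135 stood at percentile 100 of lists matched on this length in each of the 4 comparisons, which cannot decide on transcript length. It also stood at percentile 100 of lists matched on mean level over all 12 libraries, with the phases pooled. Level within a phase was not matched, so this cannot decide on background reads for these genes. The 349 tested identifiers not matched to the annotation had medians of -0.80 and -0.56 in log phase and -0.11 and 0.028 at 48 h in the mms2 and ysf3 deletions. A difference in background between the libraries thus stays open. Fold changes rose across genes with GC content, also taken over the gene with its introns. The rank correlations were 0.287 and 0.226 in log phase and 0.152 and 0.215 at 48 h in the mms2 and ysf3 deletions. The ribosomal protein genes stood at percentile 100 of lists matched on this GC content, so it does not account for them. GC content of the spliced transcripts was not matched. The alpha mating type of wild-type strain 1 is not the whole of it, because at least 64.0% of each median was kept without that strain, although the calls of single genes at 48 h ended. For the small nucleolar RNAs a length bias stays open. The rank correlation of length with fold change was 0.0611 and 0.0234 in log phase and -0.346 and -0.171 at 48 h in the mms2 and ysf3 deletions. A difference in library preparation, which is not in the labels, and the genotype itself stay open for the ribosomal protein genes and the small nucleolar RNAs alike.

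One log phase library of the ysf3 deletion, replicate 2, had high counts of 15S ribosomal RNA, at 1637 CPM against 8.20 in replicate 1. The tables argue against RNA of a 48 h culture, since stationary phase genes in that library stood at a median of 4.48% of their 48 h level. Incomplete removal of ribosomal RNA is a candidate explanation, as RDN37-2 had 743 counts there and at most 2 in the other log phase libraries. No biological explanation was tested.

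Alpha-cell genes were expressed in both libraries of wild-type strain 1. On a swap with a deletion strain, 0 of the 8 deletion libraries had more STE3 than STE2, which decides nothing, since the wild-type strain in such a swap need not be an alpha strain. On the second principal component strain 1 stood at -26.6 in log phase and -37.5 at 48 h, beside -37.6 and -13.8 in strain 2. The deletion libraries ran from 8.73 to 23.7. This argues against a swap as far as that component follows genotype, but a difference in library preparation could also produce it. A mixture of cell types would leave a-cell genes in strain 1, and the median of the 5 tested a-cell genes (STE2, STE6, BAR1, AGA2 and ASG7) in log phase was 2.59% of that in strain 2, which argues against it there, although ASG7 stood at 20.3%. At 48 h the median was 13.3%, from 9.24% for AGA2 to 38.3% for STE6, which does not decide, so a mixture stays open for that library. Whether strain 1 was meant to be an alpha strain is not in the labels.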

How the results depend on the processing

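Counts of changed genes were recomputed under each alternative, and the cause of a difference was not tested unless said. By the DESeq2 Wald test the mms2 deletion had 978 genes at 48 h and the ysf3 deletion 452, the deletions differed in 4 genes in log phase and 11 at 48 h, the mms2 interaction had 19, and the deletions shared 323 higher and 39 lower genes at 48 h. At an adjusted p under 0.001 the phase changes kept 2510, 2333 and 2438 genes in the wild type, the mms2 and the ysf3 deletion, and the 4 comparisons with the wild type and the 4 shared counts kept 0. Against a fold of 1.5 the mms2 deletion kept 9 genes in log phase and 4 at 48 h and the ysf3 deletion 116 and 0. With only the libraries compared the mms2 deletion had 235 genes at 48 h and the ysf3 deletion 620 in log phase and 547 at 48 h, and the ribosomal protein median of the mms2 interaction was 0.11.

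With strain number as a replicate block the mms2 deletion had 390 genes at 48 h and the ysf3 deletion 0. The labels give no link between equal numbers of different genotypes, and the residual r of equal numbers was 0.0673, -0.0737 and 0.103 in log phase and 0.302, 0.0378 and 0.111 at 48 h (wild type with mms2, wild type with ysf3, mms2 with ysf3). Number 1 was the shallower library of each genotype at 48 h, with 4871513, 5051438 and 9075505 counts. With strain as a replicate block in the phase comparisons, list calls that changed were hexose transporters in the wild type (0.0573 to 0.0466 as adjusted p), ribosomal proteins with an intron (0.0647 to 0.0422) and a-cell genes (0.19 to 0.00174) in the mms2 interaction, and heat shock proteins (0.0987 to 0.041), a-cell genes (0.271 to 0.00523) and SF3b and spliceosome genes (0.0402 to 0.0571) in the ysf3 interaction, and it changed no other call of the 40 lists. That block also ended the phase calls of MMS2 in the wild type and of YSF3 in the mms2 deletion. With the wild-type strain numbers crossed, 4212 genes changed with phase in the wild type.

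With wild-type strain 1 left out, chosen after the data were seen, 0 genes passed at 48 h in either deletion, the deletions shared 0 higher and 0 lower genes at 48 h, and the ribosomal protein median of the mms2 interaction turned to -0.22. With an estimated correlation the ribosomal protein calls were lost at medians of -2.67, 0.66, 0.83, 0.75, 0.49 and -0.15.

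When 1 library was left out, the lone sample left in a group was assumed to vary like the other groups. Changed genes ranged from 3559 to 3672 for the wild-type phase change, 3416 to 3469 and 3386 to 3934 for the mms2 and ysf3 deletions, 0 to 1425 and 0 to 795 for the mms2 deletion against the wild type in log phase and at 48 h, 38 to 1464 and 0 to 219 for the ysf3 deletion, 0 to 0 between the deletions in each phase, and 0 to 2 and 0 to 3 for the mms2 and ysf3 interactions. The shared counts ranged from 0 to 646 higher and 0 to 475 lower in log phase, and from 0 to 177 and 0 to 20 at 48 h. Ribosomal protein medians ranged from -2.96 to -2.50 for the wild-type phase change, 0.58 to 0.83 and 0.59 to 1.00 for the mms2 deletion in log phase and at 48 h, 0.50 to 1.02 and 0.31 to 0.73 for the ysf3 deletion, -0.051 to 0.38 for the mms2 interaction and -0.42 to 0.079 for the ysf3 interaction, which turned to 0.079 without replicate 2 of the wild type at 48 h and to 0.07 without replicate 1 of the ysf3 deletion in log phase. MMS2 ranged from 0.36 to 0.45 in log phase and from -0.10 to 0.28 at 48 h in the mms2 deletion, and YSF3 from 0.41 to 1.11 and from -0.17 to -0.01 in the ysf3 deletion.

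In the wild-type phase change MF(ALPHA)1 turned to 4.15 and SAG1 to 0.47 without replicate 1 in log phase, and to 0.52 and 0.16 without strain 1, and STE2 turned to 1.72 without replicate 2 in log phase. Over all such runs MF(ALPHA)1 ranged from -8.59 to 4.15, SAG1 from -5.08 to 0.47 and STE2 from -5.78 to 1.72. These signs turned with the log phase library that was left out, and leaving out either 48 h library turned none of them. Of the other values for named genes, 558 held, 230 were weaker and 1 was stronger when 1 library was left out, and 688 held and 66 were weaker under other settings.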

Other observations

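Of the auxotrophic marker genes, URA3, LYS2 and HIS3 had 0 counts in all 12 libraries, while LEU2 had 5767 to 30784 counts and MET17 had 1273 to 32466. The RNA of the U2 snRNA gene LSR1, named after its values were seen, made up 3.21% of counts in the wild type in log phase and 10% at 48 h, against 1.52% and 7.13% in the mms2 deletion and 1.47% and 6.76% in the ysf3 deletion.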
